A study of Mus musculus with 20 samples.

How the data were processed

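Total RNA from the livers of 20 female C57BL/6 mice was labelled with biotin by a sense-target method for whole transcripts and measured on 1-colour Affymetrix arrays, per the labels. The mice formed 5 groups of 4: saline, and the antisense oligonucleotides SPC4955, SPC4061 and SPC3847 at 10 mg/kg and SPC3833 at 5 mg/kg. An antisense oligonucleotide is a short synthetic nucleic acid strand made to pair with an RNA of matching sequence. The labels give only code names, so no target or chemistry is stated here. All mice were dosed into a vein on 3 consecutive days. The labels place the collection of livers on day 3 in the treatment protocol, counted from a first dose on day 0, and 4 days after the first dose in the source name.

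The authors deposited log2 intensities that were already summarised to 1 value per gene and array, as the values themselves show. The arrays shared neither the same median nor the same width of distribution. Array medians lay between 6.37 and 6.53, and single values between 2.38 and 13.9. The affy package was used according to the submitters' processing notes. The background correction, the normalization and the assignment of probes to genes are not given in the sources used here. They bear on the results because the distributions differed in width between arrays, and a wider one places bright genes higher and dim genes lower. The quartile range of an array lay between 2.70 and 3.21. The largest axis of variation among the arrays (principal component 1, 23.8% of the variance) correlated at 0.972 in size with this range. Signal over background per array was not analysed here, so the number of arrays sets the precision.

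The rows carry Ensembl mouse gene identifiers, and the files used here do not pair them with symbols. Of these identifiers, 0 were found in the gene table at hand, an annotation of GRCm38.p6. The 39 gene lists fixed before the data were examined, cell type markers among them, were therefore not tested, and neither was the length of primary transcripts. The planned rule named the 10 largest rises and falls against saline, and 3 in each direction between oligonucleotides. Without symbols it was reduced to the 2 largest rises and the 2 largest falls against saline. As planned, each gene had to pass the threshold, and its 4 treated arrays had to lie beyond all 4 saline arrays in that direction.

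One linear model over the 20 arrays, with a mean per group, was fitted to the deposited log2 values of 22361 genes with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with the default prior). It had 15 residual degrees of freedom. Each oligonucleotide was compared with saline, giving 4 comparisons, and with every other oligonucleotide, giving 6. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and genes with an adjusted p below 0.05 were counted. Counts were also made for changes of at least 2-fold. No gene was filtered out and no further normalization was applied. The plan allowed this if the arrays already shared a distribution or a median, which held only approximately. A gene was called specific to an oligonucleotide when it passed the threshold against saline and, in the same direction, against each of the other 3. This definition was added after the data had been seen.

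The model was tested on simulated data with 200 changed genes among 22361, drawn with a spread per gene pooled over all groups. For changes of 0.5 on the log2 scale it recovered 75.0% with SPC4955, 75.0% with SPC3833, 69.1% with SPC4061 and 83.8% with SPC3847. For changes of 1 it recovered between 97.0% and 98.5%. False calls made up 3.72% of calls with SPC4955, 10.4% with SPC3833, 2.76% with SPC4061 and 5.56% with SPC3847. Each comparison had a single draw with the same spread per gene, so differences between the oligonucleotides here are not properties of them. Genes were drawn independently, so these rates do not cover errors that genes of an array share. Nor do they cover the unlike spread of the groups, with a median SD of 0.0954 with SPC3833, 0.129 with saline and 0.152 with SPC3847. The main fit pools the spread in the same way, so these rates do not vouch for its calls.

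Comparisons against the same saline arrays share the error of those arrays. The correlation and overlap of changes between oligonucleotides were therefore set beside 50 simulated draws without effects. They were also set beside the 6 ways of giving each oligonucleotide its own 2 saline arrays. The alternatives were median centring, quantile normalization, filters on dim rows, a fit of only the 8 arrays compared, array quality weights, a trended robust prior, the ordinary statistic, the replicate number as a block, and leaving out each array. Leaving out saline replicate 1 and SPC4955 replicate 1, leaving out these and SPC3847 replicate 4 (the 3 arrays farthest from their group), and the width of each array's distribution as a covariate, were added after the data had been seen.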

Results

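Gene expression was measured in the livers of 20 mice, 4 given saline and 4 given each of 4 antisense oligonucleotides on 3 consecutive days. The stated purpose was to find expression changes in liver relative to saline. The values are log2 intensities of 22361 genes, with 1 array per mouse. Correlations across genes between arrays of 1 group lay between 0.983 and 0.997. Genes are given by Ensembl identifier because the files used here do not pair identifiers with symbols.

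With SPC4955 at 10 mg/kg, genes that changed by at least 2-fold were mostly lower than with saline: 77 were lower and 19 were higher. The largest fall was in ENSMUSG00000028127, from 12.05 ± 0.05 with saline to 7.28 ± 0.32 with SPC4955 (log2 intensity, mean ± SD, n = 4 each), a fall of 27.3-fold (limma adjusted p = 1.77e-16). ENSMUSG00000001576 fell 8.47-fold, from 10.69 ± 0.06 to 7.60 ± 0.29 (limma adjusted p = 6.76e-14). Both were also lower with SPC4955 than with each of the other 3 oligonucleotides (highest limma adjusted p of the 3 tests, 4.3e-16 and 9.86e-14). With the other oligonucleotides, ENSMUSG00000028127 differed from saline by -0.22, 0.00 and -0.08 on the log2 scale, and none of these passed the threshold. ENSMUSG00000029372 rose 3.91-fold, from 5.70 ± 0.22 to 7.67 ± 0.73 (limma adjusted p = 4.37e-05), and was higher than with each other oligonucleotide (highest limma adjusted p = 0.000871). Its level was 8.70 in SPC4955 replicate 1, an array that stood apart from its group, and 7.04 to 7.63 in the others. Without that array its rise was 1.62 on the log2 scale, against 1.97 with it. ENSMUSG00000034774 rose 3.83-fold (limma adjusted p = 1.39e-05). This gene rose 4.35-fold with SPC4061 too (limma adjusted p = 6.37e-06), and the difference between the 2 oligonucleotides did not pass the threshold (adjusted p = 0.72). Without a minimum change, 943 genes were higher and 530 lower, with a median change of 1.30-fold. After median centring the counts were 439 higher and 416 lower, after quantile normalization 753 and 727, and in a fit of only the 8 arrays 339 and 318. The number higher was 535 without saline replicate 4, 565 without SPC4955 replicate 2 and 614 without SPC4955 replicate 4.

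With SPC3833, given at 5 mg/kg, 84 genes were at least 2-fold lower than with saline and 6 were at least 2-fold higher. ENSMUSG00000027577 fell 10.0-fold, from 9.75 ± 0.48 to 6.43 ± 0.10 (log2 intensity, n = 4 each; limma adjusted p = 3.81e-05). It also fell 6.70-fold with SPC4955 (limma adjusted p = 0.000315), where the arrays varied more (SD 1.10). ENSMUSG00000031196 fell 8.99-fold, from 9.55 ± 0.08 to 6.38 ± 0.14 (limma adjusted p = 1.41e-12). It was lower than with each other oligonucleotide (highest limma adjusted p = 2.19e-10), and it fell by less with those, 1.72-fold with SPC4955, 1.88-fold with SPC4061 and 1.78-fold with SPC3847. The largest rises were shared with the other oligonucleotides. ENSMUSG00000091119 rose 2.71-fold (limma adjusted p = 0.00147), and between 2.17-fold and 2.46-fold with the other 3, from a saline level of 4.65 ± 0.34 that lay below the first quartile of every saline array. ENSMUSG00000002289 rose 2.58-fold (limma adjusted p = 0.00131), and between 1.95-fold and 2.86-fold with the other 3. Without a minimum change, 830 genes were higher and 749 lower, an order that turned in several fits. Median centring gave 344 higher and 650 lower, the fit of only the 8 arrays 668 and 745, and the replicate number as a block 688 and 711. The order was kept with the width of each array's distribution as a covariate (1568 higher and 959 lower) and with array quality weights (1317 and 1017). It turned without saline replicate 4 (593 higher and 666 lower). Without SPC3833 replicates 1, 2, 3 and 4 the counts were 499 and 602, 600 and 602, 582 and 609, and 534 and 536.

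With SPC4061 at 10 mg/kg, 36 genes were at least 2-fold higher and 36 at least 2-fold lower, a balance that leaned either way with the processing (39 and 26 after median centring, 37 and 28 with array quality weights, 30 and 38 after quantile normalization, 27 and 45 with the width of each array's distribution as a covariate). The rises reached further than with the other oligonucleotides. ENSMUSG00000038092 rose 24.8-fold, from 5.08 ± 0.52 to 9.72 ± 0.36 (log2 intensity, n = 4 each; limma adjusted p = 1.69e-08). ENSMUSG00000066071 rose 11.7-fold, from 4.18 ± 0.13 to 7.73 ± 0.59 (limma adjusted p = 2.36e-09). The saline level of ENSMUSG00000066071 lay below the first quartile of every saline array (4.97 to 5.17), and that of ENSMUSG00000038092 lay within this range. Signal over background was not analysed here, so these folds are ratios of deposited values whose lower ends may hold background, not exact ratios of RNA. Both were higher with SPC4061 than with each other oligonucleotide (highest limma adjusted p = 2.75e-07 and 1.64e-09). ENSMUSG00000038092 was 2.26-fold higher with SPC3833 (limma adjusted p = 0.024), but single arrays of SPC3833 overlapped those of saline. ENSMUSG00000038656 fell 10.6-fold, from 9.55 ± 0.89 to 6.14 ± 0.52 (limma adjusted p = 0.000255), and ENSMUSG00000035284 fell 4.32-fold, from 8.81 ± 0.14 to 6.70 ± 0.17 (limma adjusted p = 1.79e-11). Both were lower than with each other oligonucleotide (highest limma adjusted p = 0.00529 and 1.99e-11). Changes of at least 4-fold were found in 4 genes higher and 4 lower. Without a minimum change, 1952 genes were higher and 613 lower, so that 76.1% of the changed genes were higher. This share was 83.1% after median centring (1894 and 386), 62.1% after quantile normalization (1345 and 821), 63.2% with the width of each array's distribution as a covariate, where 1298 were higher, and 64.6% with array quality weights (3298 and 1806). The lower count was 1331 without the 3 arrays farthest from their group. The higher count was 1269 without saline replicate 3 and 1231 without saline replicate 4; without SPC4061 replicate 4 the counts were 1260 higher and 403 lower.

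With SPC3847 at 10 mg/kg the fewest genes passed the threshold, 28 of them at least 2-fold lower than with saline and 3 at least 2-fold higher. Of the 35 splits of these 8 arrays, 1 other than the real one called more genes of any size, 5129 against 745, so chance cannot be excluded for this count. ENSMUSG00000064857 fell 3.74-fold, from 9.64 ± 0.52 to 7.74 ± 0.32 (log2 intensity, n = 4 each; limma adjusted p = 8.74e-05). ENSMUSG00000064617 fell 3.15-fold (limma adjusted p = 0.00112). With SPC3833, ENSMUSG00000064857 fell 2.61-fold and ENSMUSG00000064617 fell 2.69-fold (limma adjusted p = 0.000544 and 0.00104), and neither gene differed past the threshold between SPC3833 and SPC3847 (limma adjusted p = 0.21 and 0.74). With SPC4061, ENSMUSG00000064857 fell 1.62-fold (limma adjusted p = 0.0493), and ENSMUSG00000064617 was 1.57-fold lower without passing the threshold (adjusted p = 0.101). ENSMUSG00000091119 rose 2.32-fold (limma adjusted p = 0.0134) and ENSMUSG00000039220 rose 2.19-fold (limma adjusted p = 0.00324). In a fit of only the 8 arrays, ENSMUSG00000064617, ENSMUSG00000091119 and ENSMUSG00000039220 no longer passed (limma adjusted p = 0.0648, 0.0959 and 0.0851), while ENSMUSG00000064857 did. Over all alternatives the adjusted p of these 3 genes ranged from 0.000226 to 0.0648, from 0.00184 to 0.0959 and from 0.000107 to 0.0851. Without a minimum change, 411 genes were higher and 334 lower. These counts depended strongly on the fit: 5 higher and 35 lower with only the 8 arrays, 180 and 182 after median centring, and 1017 and 660 with the width of each array's distribution as a covariate. The changes of at least 2-fold in the fit of only the 8 arrays numbered 9 lower and 1 higher. Without SPC3847 replicate 4, 16 genes were at least 2-fold lower, and without saline replicate 2, 7 were at least 2-fold higher. Among all changes, 201 were higher and 226 lower without saline replicate 3, 200 and 263 without saline replicate 4, 287 and 395 without SPC3847 replicate 1 and 184 and 243 without SPC3847 replicate 3, so that the order turned, and 219 were lower without SPC3847 replicate 2. With 1 array left out or under other settings, no named gene of any oligonucleotide changed direction. The named genes were chosen with arrays that did not overlap, so leaving out or weighting arrays could not turn a direction. Only median centring, quantile normalization and the covariate could.

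**Figure D1:**
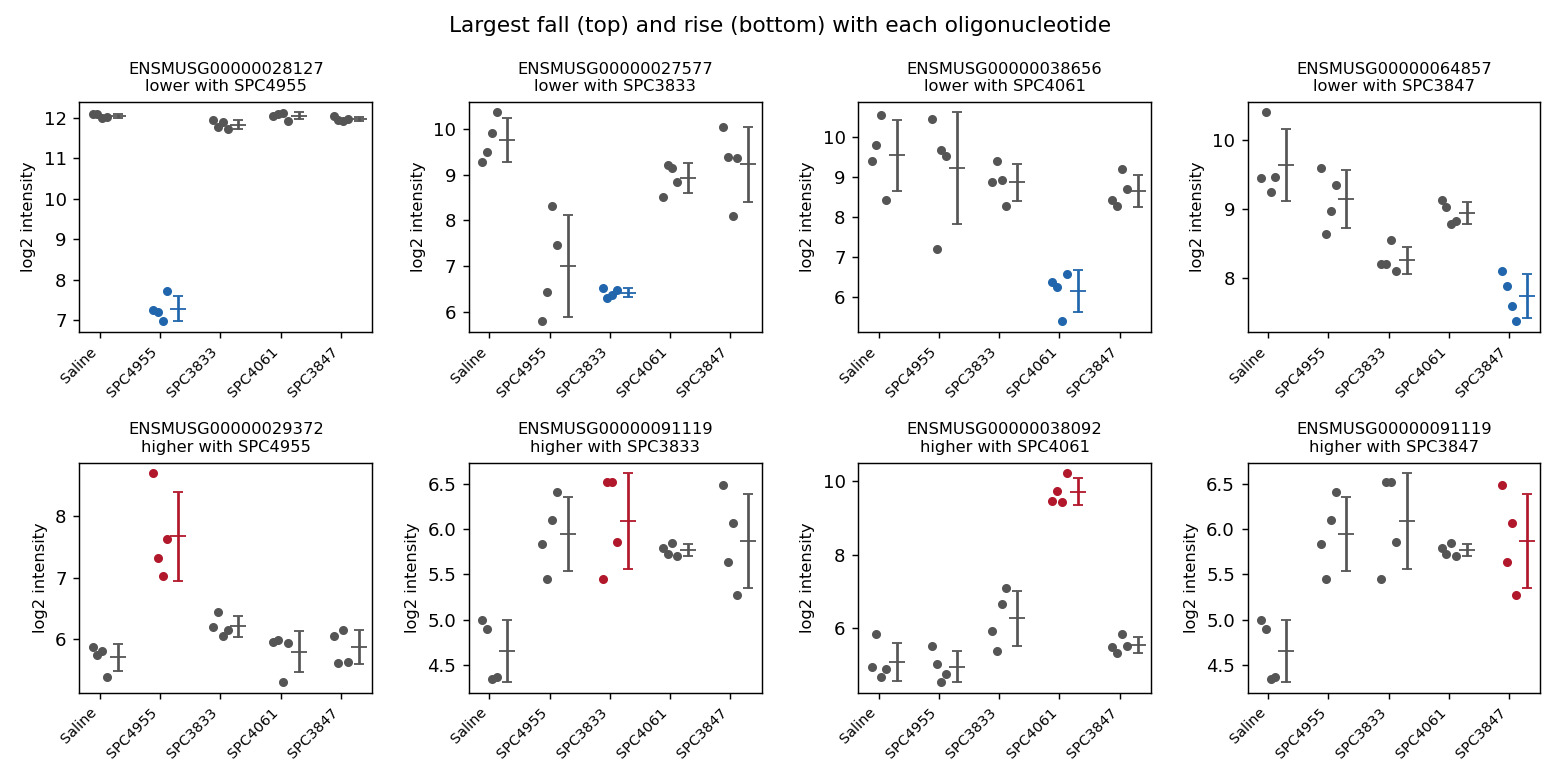
Log2 intensity (y axis) of the gene with the largest fall (top) and the largest rise (bottom) for each oligonucleotide, by group (x axis). Points are single arrays, 4 per group, and bars are the mean ± SD; coloured points mark the oligonucleotide for which the gene was chosen. ENSMUSG00000028127 stands at 7.28 with SPC4955 and near 12 in the other groups, whereas ENSMUSG00000091119 was higher with all 4 oligonucleotides.

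Among all genes called against saline, those lowered by an oligonucleotide were more often specific to it than those raised by it, where specific means different from saline and, in the same direction, from each of the other 3. The contrast was smaller at matched size: over the 4 oligonucleotides the share specific of lowered genes was 3.17 times that of raised genes, but 1.54 times (37.6% of 731 against 24.4% of 639) among changes of 0.5 to 1 on the log2 scale. By calls against saline alone the shares were close, since 71.0% of 2930 raised and 74.9% of 1670 lowered genes were called with only 1 oligonucleotide. With SPC4955, 194 of 530 lowered genes (36.6%) and 76 of 943 raised genes (8.06%) were specific. The shares were 31.4% of lowered and 5.06% of raised genes with SPC3833, and 18.9% and 1.70% with SPC3847. With SPC4061, 153 of 613 lowered genes and 253 of 1952 raised genes were specific. The odds ratio was 6.58 with SPC4955, 8.57 with SPC3833, 2.23 with SPC4061 and 13.4 with SPC3847 (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p over the 4 tests between 6.01e-45 and 1.1e-11). Genes are not independent replicates, so these p-values describe the gene sets and not the mice. Of 52 combinations of oligonucleotide and setting, the reported ones included, 51 had the larger share among lowered genes. With array quality weights the order turned for SPC4061, with 11.5% of lowered and 12.2% of raised genes specific. Among changes of at least 2-fold, the lowered genes that were specific numbered 53 of 77 with SPC4955, 45 of 84 with SPC3833, 19 of 36 with SPC4061 and 8 of 28 with SPC3847. The raised ones numbered 7 of 19, 0 of 6, 19 of 36 and 0 of 3. With SPC3847 the 8 became 3 in the fit of only the 8 arrays and 16 without SPC3847 replicate 1.

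**Figure D2:**
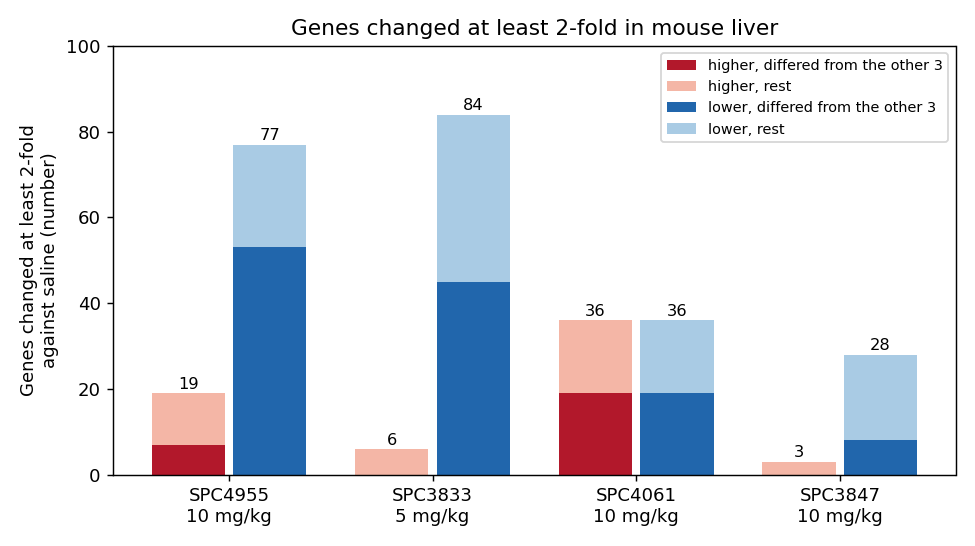
Number of genes (y axis) that differed from saline by at least 2-fold with each oligonucleotide (x axis, with its dose), limma adjusted p below 0.05, n = 4 mice per group. Dark segments are genes that differed in the same direction from each of the other 3 oligonucleotides. Falls outnumbered rises with SPC4955 (77 and 19), SPC3833 (84 and 6) and SPC3847 (28 and 3), and numbered 36 each with SPC4061, where the balance leaned either way with the scaling (39 rises and 26 falls after median centring, 30 and 38 after quantile normalization).

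Some genes passed the threshold with every oligonucleotide: 73 were higher with all 4 and 27 were lower with all 4, where independent lists of that size would share 0.0562 and 0.00727. All 4 comparisons used the same 4 saline arrays, which cannot be divided into 4 sets of at least 2, so part of these counts may come from the shared arrays. ENSMUSG00000091119 and ENSMUSG00000002289 were among those higher, and ENSMUSG00000031196 was among those lower. Genes that passed against saline with 1 of the 4 and not with the other 3 numbered 2081 higher and 1250 lower, which does not show that the oligonucleotides differed in them. By the tests between oligonucleotides, 378 raised and 645 lowered genes were specific to 1. For SPC4955 and SPC3833, 321 genes were higher with both and 194 lower with both, where independent lists of that size would share 35.0 and 17.8. With separate saline arrays for each, 78.5 (range 64 to 108) were higher and 75.5 (range 68 to 94) lower with both on average over 6 assignments of the saline arrays, against 8.22 and 7.26 for independent lists. Simulated groups without effects shared 0 genes, but at most 1 gene passed the threshold in any simulated comparison, so this 0 says nothing about sharing. Across genes, changes correlated between 0.322 and 0.515 for the 6 pairs of oligonucleotides, and simulated groups without effects against the same saline arrays gave about 0.50. With separate saline arrays the mean correlations over the 6 assignments were between 0.0144 (SPC4955 and SPC3847, range -0.188 to 0.216) and 0.179 (SPC4061 and SPC3847, range -0.0448 to 0.295), and the range crossed 0 for 4 of the 6 pairs. The covariance of changes was 0.0117 for SPC4955 and SPC3847 and between 0.0162 and 0.0208 for the other pairs, against 0.0073 simulated. The simulation gave every group the same spread per gene. Saline arrays deviated from their group mean by 0.148 to 0.270 (SD over genes), and arrays of the oligonucleotides by 0.101 to 0.236. Saline error may thus exceed the simulated one, so neither simulated value is a firm baseline. With separate saline arrays the mean covariance was -0.000281 for SPC4955 and SPC3847 and between 0.00424 and 0.00879 for the other pairs. SPC4955 and SPC4061 shared 410 raised genes, against 82.3 for independent lists, and with separate saline arrays 88.2 on average (range 73 to 120), against 18.6.

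Among the oligonucleotides given at the same dose of 10 mg/kg, SPC4955 and SPC4061 differed by at least 2-fold in 118 genes, of which 91 were lower with SPC4955. SPC4955 and SPC3847 differed by at least 2-fold in 109 genes, 64 of them lower with SPC4955, and SPC4061 and SPC3847 in 58 genes, 37 of them higher with SPC4061. The last order turned with the width of each array's distribution as a covariate, with 20 higher and 28 lower. Without a minimum change, 801 genes were higher and 1156 lower with SPC4955 than with SPC4061. For SPC4955 against SPC3847 the counts were 1051 and 638, and for SPC4061 against SPC3847 they were 1065 and 442. The share of these genes that were higher moved with scaling, from 40.9% to 26.9% after median centring for the first pair, from 62.2% to 51.3% after median centring, 48.0% after quantile normalization and 50.8% with the width as a covariate for the second, and from 70.7% to 55.2% after quantile normalization and 54.1% with the width as a covariate for the third. Fitting only the 8 arrays gave 336 and 267 genes for SPC4955 against SPC3847 and 500 and 217 for SPC4061 against SPC3847.

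Doses differed in the comparisons with SPC3833, which was given at 5 mg/kg against 10 mg/kg for the others. For SPC3833 and SPC4061, 104 genes were at least 2-fold lower and 18 at least 2-fold higher with SPC3833; with the width of each array's distribution as a covariate these were 76 and 35. SPC4955 and SPC3833 differed by at least 2-fold in 98 genes, 53 higher and 45 lower with SPC4955, but 43 higher and 57 lower with that covariate, 51 and 52 after quantile normalization, 52 and 52 with array quality weights, and 48 and 51 without SPC4955 replicate 4. SPC3833 and SPC3847 differed in 66, 54 of them lower with SPC3833. Without a minimum change, 1659 genes were higher and 2125 lower with SPC3833 than with SPC4061, 796 higher and 505 lower with SPC4955 than with SPC3833, and 676 higher and 747 lower with SPC3833 than with SPC3847. For SPC3833 against SPC4061 these counts were 930 and 963 with the width of each array's distribution as a covariate, 5407 and 3849 with array quality weights, 693 and 2519 after median centring, 4079 and 3139 with only the 8 arrays, and 3135 and 2866 without the 3 arrays farthest from their group. For SPC4955 against SPC3833 the share higher moved from 61.2% to 49.4% after quantile normalization and 45.7% with the width as a covariate (689 and 819). For SPC3833 against SPC3847 it moved from 47.5% to 30.0% after median centring and to 55.0% with the width as a covariate (1280 and 1047); the counts were 665 higher and 527 lower without SPC3847 replicate 1, and 617 and 577 without SPC3847 replicate 3.

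Arrays of a group differed most with SPC3847 and with saline, where the median SD of a gene among the 4 arrays was 0.152 and 0.129 on the log2 scale. With 1 array per mouse, differences between mice and between arrays cannot be told apart. It was 0.120 with SPC4955, 0.102 with SPC4061 and 0.0954 with SPC3833. Among genes with a mean level above the median it was 0.143 with SPC3847, 0.117 with SPC4955 and 0.113 with saline. Saline thus ranked above SPC4955 only with the dim rows included. Saline replicate 1 had 254 genes at least 2-fold above the mean of the other 3 saline arrays, and SPC4955 replicate 1 had 202 above the other 3 of its group, against at most 29 in the remaining arrays. With these 2 arrays left out, 79 genes were at least 2-fold lower and 16 higher with SPC4955. The width of the distribution of values, taken as its quartile range, varied between 2.81 and 3.15 among saline arrays and between 2.70 and 3.16 among SPC3847 arrays. It was between 2.87 and 2.97 with SPC3833 and between 3.02 and 3.20 with SPC4061, so that these 2 groups did not overlap in it.

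**Figure D3:**
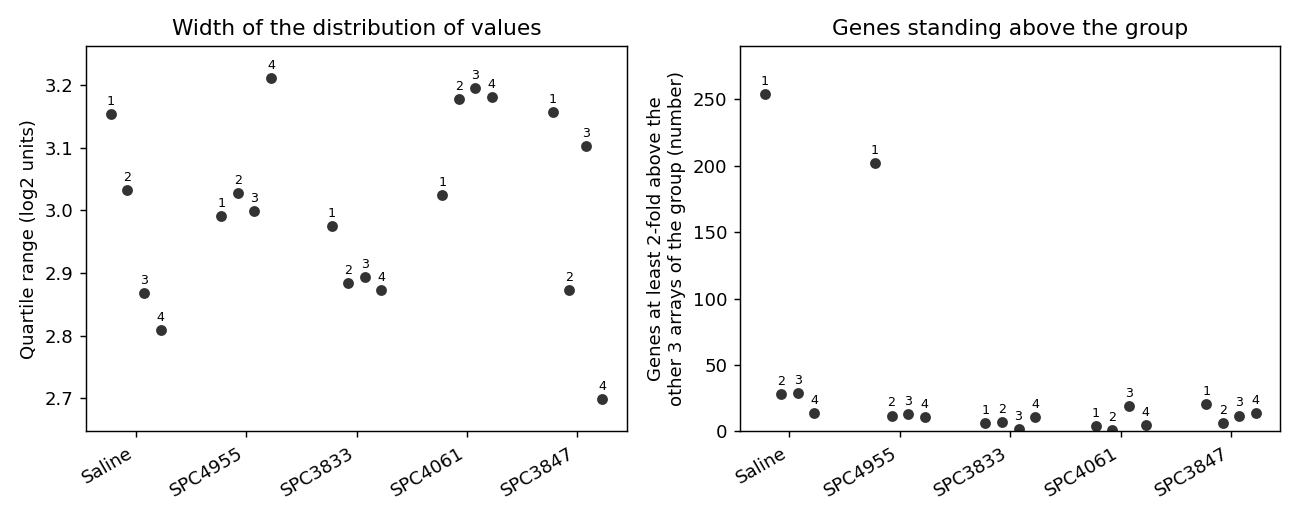
Left, quartile range of the log2 values of each array; right, number of genes at least 2-fold above the mean of the other 3 arrays of the group. Each point is 1 array, marked with its replicate number, and the x axis gives the group. Saline replicate 1 (254 genes) and SPC4955 replicate 1 (202 genes) stand above all other arrays on the right.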

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

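The test on arrays numbered 1, the covariate for the width of the distributions and the 2 patterns weighed here were chosen after the results had been seen. Of 100 sets of 4 arrays examined for an array far from the other 3, 11 had one. Independent normal values would give about 1 in 20. The sets hold genes chosen from these data and several measures of the same arrays, so no excess over chance can be read from this.

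Saline replicate 1 stood apart from the other saline arrays in the SD of its deviations from the group mean (0.270, against 0.148 to 0.163) and in its genes at least 2-fold above the others (254, against 14 to 29), and SPC4955 replicate 1 had 202 such genes, against 11 to 13. Their deviations correlated at 0.517 across genes, and 160 genes were at least 2-fold above in both, where 2.29 would be shared by independent lists. The tables argue against a property of all arrays numbered 1, since 3 of 6 correlations with the other such arrays were below 0. They also argue against the distributions of values, as the correlation was 0.574 after quantile normalization, and against an exchange of the 2 samples, as saline replicate 1 lay nearer SPC4955 at 0% of 55 specifically lowered genes. RNA from another tissue or cell population in both livers stays open. Of the genes 2-fold off in both, 99.4% lay above, but independent lists of these sizes would give 98.9%. This share thus follows from what set the arrays apart and decides nothing. The genes above in both had a median level at percentile 35.7 of the other 3 saline arrays. Their largest rises were 7.28 in saline replicate 1 and 7.39 in SPC4955 replicate 1 on the log2 scale. No bound was set for these values, and no biological explanation was tested.

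Genes higher with SPC4061 made up 76.1% of the genes that differed from saline. Dim rows near background are argued against as the whole source, because 78.7% were higher among genes with a mean level above the median. A wider distribution also places bright genes higher, so this share does not tell an effect of the oligonucleotide from the width. The median change over genes was 0.075 on the log2 scale with rows below the median left out, against -0.015 over all rows. The distribution of values of each array and a factor that follows its quartile range stay open: the share was 62.1% after quantile normalization and 63.2% with the quartile range as a covariate, between the bounds set for either reading, whereas median centring raised it to 83.1%. Part of the excess may thus lie in the width of the distributions, which was 3.02 to 3.20 with SPC4061 and 2.81 to 3.15 with saline. An effect of the oligonucleotide also stays open.

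Other arrays that stood apart in the values examined were these. SPC4955 replicate 4 had a quartile range of 3.21, against 2.99 to 3.03 in the others of its group, and SPC4061 replicate 1 one of 3.02, against 3.18 to 3.20. SPC3847 replicate 4 had 95 genes at least 2-fold below the others, against 6 to 12. The log2 intensity of ENSMUSG00000031196 was 9.67 in saline replicate 3, against 9.50 to 9.53, 8.31 in SPC4955 replicate 1, against 8.87 to 8.97, and 8.38 in SPC4061 replicate 1, against 8.72 to 8.73. ENSMUSG00000039220 was at 9.03 in saline replicate 2, against at most 8.10 in the other saline arrays. ENSMUSG00000029372 was at 5.30 in SPC4061 replicate 3, against 5.95 to 5.99.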

How the results depend on the processing

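Leaving out 2 arrays (saline replicate 1 and SPC4955 replicate 1) or 3 (also SPC3847 replicate 4), the covariate and the counts of specific genes were chosen after the data had been seen; the other alternatives were fixed before the data were examined. Of 1120 alternative counts, 973 stayed within 1.5 times the reported count and 147 did not. All 313 alternative values of the 16 gene changes named against saline kept their direction, and 310 kept their side of the threshold. Most of these directions were fixed in advance, because the genes were chosen with arrays that did not overlap. Leaving out or weighting arrays could not turn them, and the other fits and filters kept the same estimate. Only median centring, quantile normalization and the covariate could have turned a direction. The replicate numbers were not taken to pair the mice: 9 of 40 pairs of arrays with the same number had deviations that correlated above 0.1, with a median of -0.0276 and a range from -0.496 to 0.517, and 2 of 20 arrays correlated best with their own number. With the number as a block, 798 genes were higher and 488 lower with SPC4955 than with saline, 688 and 711 with SPC3833, 1678 and 526 with SPC4061, and 292 and 282 with SPC3847, and no count moved by over 1.5 times. The gene list tests and the length of transcripts were not run for want of gene symbols, and averaging several rows of a gene had nothing to act on. Signal over background was not analysed here. Except where a setting itself changes the number of genes or arrays, the cause of the changes below was not tested.

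With each array centred on a common median, the genes higher numbered 439, 344 and 180 for SPC4955, SPC3833 and SPC3847 against saline, 447 for SPC4955 against SPC4061, 574 for SPC4955 against SPC3847, 693 for SPC3833 against SPC4061 and 281 for SPC3833 against SPC3847. The genes lower numbered 386 and 182 for SPC4061 and SPC3847 against saline and 286 for SPC4061 against SPC3847. Specific genes numbered 48 higher with SPC4955, 15 higher with SPC3833, 97 lower with SPC4061 and 33 lower with SPC3847. Quantile normalization gave 666 genes higher with SPC3847 than with saline, 805 lower with SPC4955 than with SPC3833 and 1055 lower with SPC4955 than with SPC3847, and 102 and 31 specifically higher with SPC3833 and SPC3847, 1 of the latter by at least 2-fold.

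Leaving out rows with a mean level below the first quartile gave 12 genes specifically higher with SPC3847, as did the trended robust prior. Leaving out those below the median gave 646 higher with SPC3847 than with saline and 1024 higher with SPC3833 than with SPC4061. Specific genes were then 68 higher with SPC3833, 4 higher by at least 2-fold with SPC4955, and with SPC3847 14 higher, 1 higher by at least 2-fold and 107 lower.

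Fitting only the 8 arrays gave 339 higher and 318 lower for SPC4955 against saline, 5 and 35 for SPC3847 against saline, 336 and 267 for SPC4955 against SPC3847, and 500 and 217 for SPC4061 against SPC3847. It gave 4079 higher for SPC3833 against SPC4061 and 346 higher for SPC3833 against SPC3847. At least 2-fold, 1 was higher and 9 lower with SPC3847 than with saline. Specifically higher were 38, 26, 150 and 0 with SPC4955, SPC3833, SPC4061 and SPC3847, 4 with SPC4955 by at least 2-fold, and specifically lower with SPC3847 11, 3 of them by at least 2-fold.

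Array quality weights gave 1317, 3298 and 793 higher with SPC3833, SPC4061 and SPC3847 than with saline and 1806 lower with SPC4061. Between oligonucleotides they gave 1452 higher and 1090 lower for SPC4955 against SPC3833, 1443 and 1893 for SPC4955 against SPC4061, 5407 and 3849 for SPC3833 against SPC4061, and 1146 and 1505 for SPC3833 against SPC3847. Specifically higher were 117, 109, 404 and 16 with SPC4955, SPC3833, SPC4061 and SPC3847, 1 of the last by at least 2-fold, and 353 were specifically lower with SPC3833.

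The quartile range as a covariate gave 1568, 1298 and 1017 higher with SPC3833, SPC4061 and SPC3847 than with saline, 864 and 660 lower with SPC4955 and SPC3847, and 12 at least 2-fold higher with SPC4955. Between oligonucleotides it gave 819 lower for SPC4955 against SPC3833, 1229 higher for SPC4955 against SPC4061, 1226 lower for SPC4955 against SPC3847, and 930 higher, 963 lower and 35 at least 2-fold higher for SPC3833 against SPC4061. It gave 1280 higher for SPC3833 against SPC3847, and 677 higher, and 20 at least 2-fold higher and 28 at least 2-fold lower for SPC4061 against SPC3847. Specifically higher were 92, 160 and 37 with SPC3833, SPC4061 and SPC3847, by at least 2-fold 3, 1 and 1 with SPC4955, SPC3833 and SPC3847, and 293 were specifically lower with SPC4955. Leaving out 2 arrays gave 4 specifically higher by at least 2-fold with SPC4955. Leaving out 3 gave 1331 lower with SPC4061 and 782 higher with SPC3847 than with saline, 5 of these by at least 2-fold. It gave 1212 higher for SPC4955 against SPC3833, 28 at least 2-fold higher for SPC4955 against SPC3847, 3135 higher for SPC3833 against SPC4061, 1235 lower for SPC3833 against SPC3847, and 14 specifically higher with SPC3847, 2 by at least 2-fold.

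With each array left out in turn, the genes higher ranged from 535 to 1020, 499 to 702, 1231 to 1879 and 184 to 568 for SPC4955, SPC3833, SPC4061 and SPC3847 against saline. They ranged from 660 to 1183 for SPC4955 against SPC3847 (660 without SPC3847 replicate 2), 775 to 1648 for SPC3833 against SPC4061, 449 to 665 for SPC3833 against SPC3847 (449 without SPC3833 replicate 3 or SPC3847 replicate 2) and 655 to 1423 for SPC4061 against SPC3847. For SPC3833 against SPC4061 the count was 906, 976 and 869 without SPC3833 replicates 2, 3 and 4, and 775, 936 and 850 without SPC4061 replicates 2, 3 and 4. For SPC4061 against SPC3847 it was 683 and 655 without SPC4061 replicates 2 and 4, and 668 and 675 without SPC3847 replicates 2 and 4. The genes lower ranged from 403 to 676 and 219 to 395 for SPC4061 and SPC3847 against saline, and 273 to 653 for SPC4061 against SPC3847 (282 and 273 without SPC4061 replicates 2 and 4). Genes at least 2-fold higher ranged from 2 to 7 for SPC3847 against saline (7 without saline replicate 2, 6 without SPC3847 replicate 1) and 9 to 22 for SPC3833 against SPC3847 (22 without SPC3847 replicate 1), and those at least 2-fold lower from 16 to 37 for SPC3847 against saline. Genes specifically higher ranged from 48 to 82 with SPC4955 (48 without its replicate 2), 21 to 39 with SPC3833 (24, 21 and 25 without its replicates 2, 3 and 4), 157 to 260 with SPC4061 (168 and 157 without its replicates 2 and 4) and 4 to 9 with SPC3847 (4 without saline replicate 2, 3 or 4). By at least 2-fold they ranged from 3 to 8 with SPC4955 (4, 3 and 4 without saline replicates 2 and 4 and SPC4955 replicate 1) and 0 to 1 with SPC3847 (1 without saline replicate 2 or SPC3847 replicate 1). Genes specifically lower with SPC3847 ranged from 36 to 95 (95 and 36 without its replicates 1 and 2), and by at least 2-fold from 6 to 16.

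With separate saline arrays for each oligonucleotide, the correlation of changes was 0.152 for SPC4955 and SPC3833, 0.152 for SPC4955 and SPC4061, 0.0144 for SPC4955 and SPC3847, 0.0817 for SPC3833 and SPC4061, 0.164 for SPC3833 and SPC3847 and 0.179 for SPC4061 and SPC3847, as means over 6 assignments of the saline arrays whose ranges crossed 0 for 4 of the 6 pairs; it removes the error of saline arrays that the comparisons share.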

Other observations

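The definition of specific genes, and so the tests on it, was chosen after the results had been seen.

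Among all genes called, of those lowered by an oligonucleotide a larger share was specific to it than of those raised, 29.0% of 2226 against 9.14% of 4136 over the 4 oligonucleotides. Dim rows near background are argued against, because the ratio of the shares was 3.91 (95% interval 3.45 to 4.44) among genes with a mean level above the median. The 95% intervals given here treat every call as independent. A gene can count with several oligonucleotides and all calls share the saline arrays, so the intervals are likely too narrow. Error of the saline arrays shared by all comparisons is argued against as the whole source of the shared rises, because raised genes found with 2 saline arrays were higher by a median of 0.16 on the log2 scale with the other oligonucleotides against the other 2 saline arrays, and by more than 0.1 in 22 of 24 such sets (range 0.0436 to 0.243). The 24 sets reuse the same saline and treated arrays, so they are not independent of each other. Lowered genes carried over at a similar size, with a median of -0.116, a range from -0.226 to 0.0838 and 16 of 24 sets beyond 0.1, so this test does not tell rises from falls, and a part of that error in the difference between them stays open. The size of falls stays open: among changes of 0.5 to 1 on the log2 scale the ratio was 1.54 (95% interval 1.31 to 1.82), so part of the difference may come from falls being larger and passing more tests, and separate targets of the oligonucleotides stay an untested hypothesis.

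Other splits of the 8 arrays of each comparison were fitted, 35 per comparison with the real one. For SPC4955, SPC3833 and SPC4061 against saline only the real split, 1 of 35, gave as many genes (1473, 1579 and 2565, against at most 1, 2 and 2 in the others). The counts thus followed the groups more than any other split. But 1 of 35 is the smallest share possible here, and it was not adjusted for the number of comparisons. Splits that mix the groups also carry the group difference in their spread, which lowers their counts. The splits therefore do not exclude chance. Between oligonucleotides too, only the real split, 1 of 35, gave as many genes in each comparison: 1301 against at most 2 for SPC4955 and SPC3833, 1957 against 5 for SPC4955 and SPC4061, and 1689 against 350 for SPC4955 and SPC3847. It was 3784 against 0 for SPC3833 and SPC4061, 1423 against 2 for SPC3833 and SPC3847, and 1507 against 2 for SPC4061 and SPC3847. The arrays of SPC3833 and SPC4061 did not overlap in quartile range, so the splits of this pair cannot tell the groups from the width. With the quartile range as a covariate, 1893 genes were called for this pair, 1446 of them among the 3784. For SPC3847 against saline, 2 of 35 splits gave as many genes as the real 745, so chance cannot be excluded. The other one set saline replicates 1 and 2 and SPC3847 replicates 1 and 3 against the remaining 4 arrays and gave 5129 genes. Those 4 arrays had quartile ranges between 3.03 and 3.16 and the remaining 4 between 2.70 and 2.87, which points to a structure of the samples that crosses the groups. With the quartile range as a covariate the real comparison gave 1017 genes higher and 660 lower.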
